A study of Cavia porcellus with 9 samples.

How the data were processed

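Retinas of male guinea pigs (Cavia porcellus) of the Dunkin-Hartley strain, reared for 8 weeks under green, blue or white light and sampled at 12 weeks of age, were profiled by RNA sequencing. Per the labels' protocols, the retinas were frozen on dry ice, RNA was extracted with Trizol and paired-end libraries were sequenced on an Illumina HiSeq instrument. The authors deposited a table of whole-number counts, with 19962 genes in rows and 9 libraries in columns, per the file headers. The aligner, the counting tool, its strand setting, the genome build and the annotation are not given in the sources used here.

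The deposited counts sum to between 62155041 and 74979806 per library. They were taken as raw counts because they are whole numbers whose totals differ between libraries. Low counts are unevenly spread. Over all libraries, 2014 values equal 4 and 472 equal 3, 1267 equal 8 and 410 equal 7, and 859 equal 12 and 349 equal 11. A unit of the table is therefore not certain to be a single sequenced fragment, and the fits were repeated after dividing the counts by 4, an alternative chosen after seeing the data. The tests had been planned for normalized values (limma on a log2 scale), with edgeR as the planned test if the table held counts. Since it did, edgeR was used, and the alternatives that exist only for normalized values (other pseudocounts, quantile normalization) were not run.

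Each light group has 3 libraries. In each group 2 of the 3 library titles carry the same animal number (11 in green, 32 in blue and 6 in white), so the 9 libraries stand for 6 animal labels and 2 per group. The labels of library 1 of blue (2R-23) and library 3 of white (R-23) share the part R-23; whether they name the same animal is not stated, and they were taken as different. The titles of library 1 of green and library 3 of white end in "-B", whose meaning is not given in the sources used here. It is also not stated whether the 2 green libraries numbered 11, both titled as the right eye, come from the same eye. The p-values treat the 3 libraries of a group as independent and so measure the spread between libraries, which is partly a spread between eyes of an animal. Libraries are numbered 1 to 3 within a group in the order of their deposition, and these library numbers pair nothing across groups.

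All 9 libraries entered a single fit in edgeR 4.0.16 (R 4.3.3) with the light group as the only term. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 15469 genes; 4493 were removed, of which 2697 had no count in any library. Library sizes were scaled by TMM factors, and quasi-likelihood F tests gave the contrasts green minus white, blue minus white and green minus blue, and a joint test of any difference among the 3 groups. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Levels are CPM (counts per 10 to the power of 6 counts) scaled by TMM, given as mean ± SD over 3 libraries, and log2 fold changes carry a standard error (SE) derived from the fold change and its F statistic. The common biological coefficient of variation was 17.68%. A count of 0 in a library allows a level of up to 0.04 to 0.0483 CPM (3 counts of the library's total). Such floors cover counting error only, and would be too low if a unit of the table is less than a fragment.

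Gene lists and the rule for naming genes were written before the data were examined. They cover, among others, rod and cone phototransduction, the visual cycle and pigment epithelium, Müller glia, microglia, vascular cells, lens, melanopsin cells, the circadian clock, dopamine, retinoic acid, immediate early genes, eye growth signals, GABA and glycine transmission, calcium and sodium channels, potassium channels, glycolysis, oxidative phosphorylation, ribosomal proteins, hypoxia and angiogenesis, and interferon and antigen presentation. Of 47 lists, 45 had at least 5 tested members. The list of blood cell markers had 1 tested member and that of mitochondrially encoded genes had 0, so these were not tested. Each list was tested with cameraPR of limma 3.58.1 on signed z values from edgeR, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 45 lists of a comparison. The correlation estimated from the residuals and the self-contained fry test served as alternatives. Gene symbols were used as deposited. 18339 identifiers match symbols in the names table of the assembly mCavPor4.1 and 18734 match when numbered loci are included; no coordinates are printed, because the build behind the counts is not given.

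The genes named were set by that rule. In each comparison it takes first the genes with a symbol that pass the threshold without overlap between the groups' libraries and reach 1 CPM in the higher group, then fills up to 20 with the genes of smallest unadjusted p. It adds up to 4 members of each list that passes or has a called member, and 28 fixed genes of light sensing, dopamine, growth signalling and the clock, of which 22 could be tested. No gene with a symbol passed in edgeR, so the named genes below the threshold are given as values. LOC101788254, which has no symbol, is named because it is the only gene that passed there. Rpe65, Pmel, Cryaa and other genes named in the closing section were chosen after their values were seen.

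The edgeR steps were tested on simulated data with the real genes' means and dispersions and the real library sizes. In them 80, 60 and 60 genes of at least 1 CPM were changed 1.5-fold, 2-fold and 4-fold in green, each gene drawn independently. A further, smaller set of genes was raised in green to test the list step. Calls of that set count neither as recovered nor as false. Between green and white edgeR recovered 31.2% of the genes changed 1.5-fold, 75% of those changed 2-fold and 98.3% of those changed 4-fold among 15319 genes, with 10 false calls. DESeq2 1.42.0 recovered 60%, 86.7% and 100% with 40 false calls, and limma's voom 28.7%, 76.7% and 98.3% with 11. An adjusted threshold is easier to reach with that many changed genes, so the rates can be too high where few genes change. Alternatives were the animal number as a block in voom, counts summed per animal number, no filter and a stricter filter, DESeq2's size factors and upper-quartile scaling in place of TMM, only the 6 libraries compared, robust empirical Bayes, DESeq2's Wald test, and each library left out in turn. In voom the correlation within animal numbers was estimated below 0 and set to 0, so no block entered that fit. Further alternatives chosen after seeing the data were the "-B" suffix as a covariate, both such libraries left out, the level of 5 pigment epithelium genes as a covariate, and the first 1 or 2 components of the residual log2 CPM values as covariates. Figures were drawn with matplotlib 3.10.9.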

Results

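The retinal transcriptome was measured by RNA sequencing in guinea pigs reared under green, blue or white light, with 3 libraries per light and 2 animal numbers behind each group's libraries. The series title speaks of wavelength defocus and bidirectional control of refractive development, so the comparisons are each coloured light against white and green against blue. Libraries 1 to 3 held 74545367, 65695294 and 71137817 counts in green, 70178509, 74979806 and 68372622 in blue, and 66699889, 70630932 and 62155041 in white. Between 15871 and 16145 genes had at least 1 count per library.

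Libraries of a light group were hardly closer to each other than to those of other groups. Pearson's r of log2 levels across genes averaged 0.9818 for the 3 pairs of libraries with an animal number in common, 0.9801 for other pairs within a group and 0.9794 between groups. The 3 pairs stood at 0.9864 in blue, 0.9803 in white and 0.9787 in green. The green pair, both titled as the right eye, thus lay below the mean between groups. These are correlations across genes, which are not independent replicates. No pair agreed within sampling noise, so all 9 libraries were kept as separate samples. Genes of the retinal pigment epithelium, the layer behind the retina, varied widely within groups. Rpe65, which encodes the isomerase of the visual cycle, ranged from 7.76 to 144 CPM over the 9 libraries, and the pigment cell gene Pmel from 3.89 to 95.1 CPM. Of the green libraries, 1 and 3 had 14.4 and 7.76 CPM of Rpe65 and library 2 had 102 CPM, while the blue libraries had 61, 63.8 and 98.6 CPM.

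Under green light, 1 of 15469 genes differed from white light at an adjusted p under 0.05. LOC101788254, a protein-coding locus without a symbol in the names table used, had 65, 104 and 123 counts in the green libraries and 0 in each white library. Its green level of 1.40 ± 0.498 CPM (SD, n = 3) was at least 93.3-fold above the floor of 0.015 CPM that 3 counts over the white group set (edgeR adjusted p = 0.0143). Near-identical copies elsewhere in the genome were not analysed here, so how its reads were assigned is uncertain. Next in rank was Myo15b, an unconventional myosin, at 13.5 ± 3.50 CPM in green against 4.74 ± 0.778 CPM in white. The log2 difference of 1.51 ± 0.21 (SE) did not pass (adjusted p = 0.123). All 20 genes with a symbol and the smallest p separated the 3 green from the 3 white libraries, with 15 higher and 5 lower in green. In edgeR none passed (adjusted p from 0.123 to 0.696), and 15 of the 20 were among the genes that DESeq2 called, Myo15b and Slc16a6 included.

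Among these genes below the threshold in edgeR, Slc16a6, a member of the monocarboxylate transporter family, was at 32.05 ± 4.46 CPM in green and 15.9 ± 2.48 CPM in white. Igfbp5, which encodes a binding protein of insulin-like growth factors, was at 366 ± 110 CPM against 190 ± 19.2 CPM, with log2 difference 0.95 ± 0.19. Ddit4, a stress-induced inhibitor of mTOR signalling, differed by 0.46 ± 0.09 on the log2 scale, Arrdc3 by 0.82 ± 0.19 and Cacna1f, the calcium channel of photoreceptor synapses, by 0.37 ± 0.08. Lower in green were Rbfox1, a splicing regulator, with a log2 difference of -0.78 ± 0.15, the tubulin gene Tuba8 with -1.26 ± 0.23 and Odf3 with -0.92 ± 0.20. At an unadjusted p under 0.05 stood 899 genes, 544 of them higher in green, where chance alone would give 773. Other splits of the green and white libraries into 3 and 3 gave from 186 to 2220 such genes. Groups did not overlap for 10.1% of genes, where chance gives 10% for 3 libraries against 3. The call of LOC101788254 was lost without library 2 or library 3 of blue, which only share in the estimate of spread (adjusted p = 0.0678 and 0.0656), with counts divided by 4 (0.128), in a fit of the 6 libraries alone (0.14) and in voom (0.572). DESeq2 called 24 genes, 16 higher and 8 lower. Over all alternatives the adjusted p of LOC101788254 ran from 1.47e-08 to 0.572. The count of genes was 2 without library 2 or 3 of green, 3 without library 1 or 2 of white and 6 without library 3 of white.

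**Figure D1:**
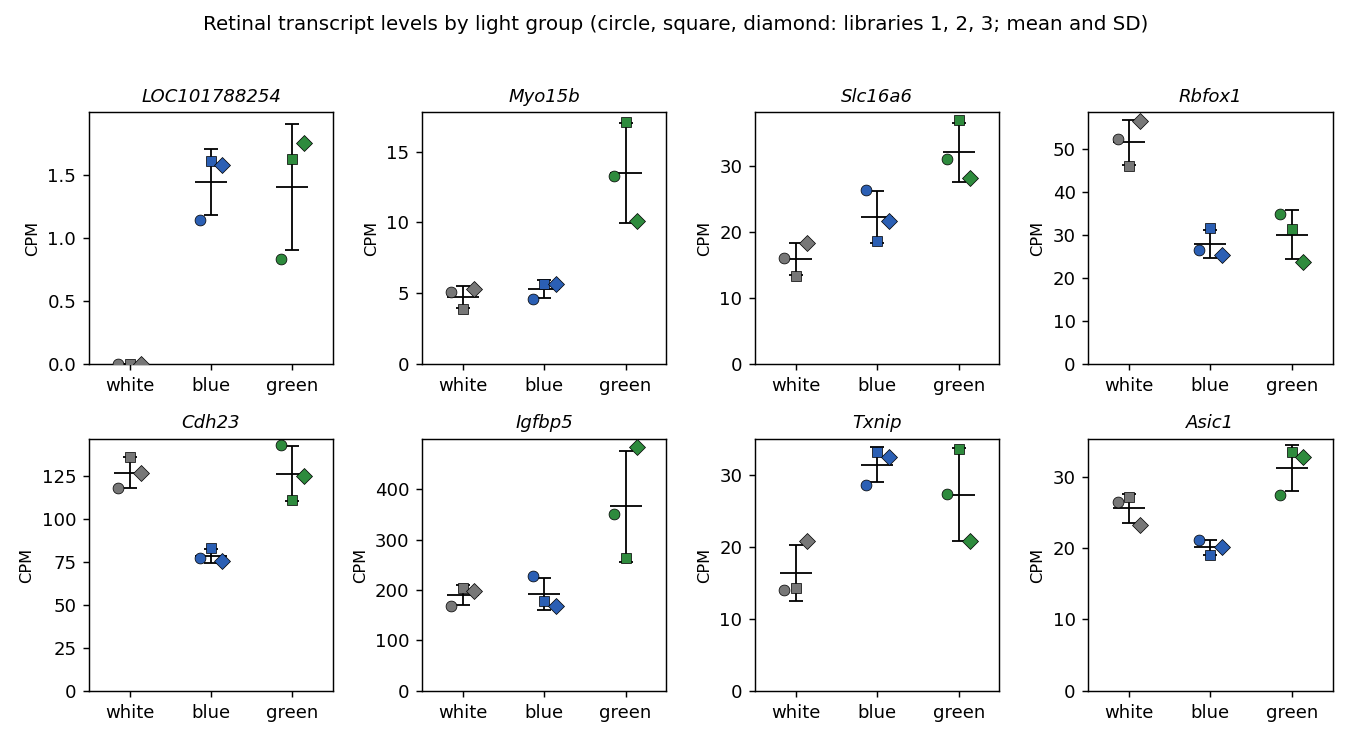
Levels in CPM of 8 genes (y axis) in the white, blue and green groups (x axis), with a symbol per library and bars for mean and SD of 3 libraries. LOC101788254 is at 0 in the white libraries, Myo15b is near 5 CPM in white and blue and at 13.5 CPM on average in green, and Cdh23 is at 78.5 CPM in blue against 127 in white and 126 in green. In edgeR LOC101788254 alone passed. DESeq2 also called Myo15b, Slc16a6, Igfbp5 and Rbfox1 in green and Cdh23, Rbfox1 and Txnip in blue, each against white. Between green and blue it called Myo15b, Cdh23, Igfbp5 and Asic1.

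Of 45 gene lists, 3 passed between green and white. The hypoxia and angiogenesis list rose in green, with 14 of 19 members higher and a median log2 difference of 0.25 (adjusted p = 6.34e-04). It also passed with an estimated correlation (adjusted p = 0.0407). Ddit4 was at 110.5 ± 7.39 CPM in green and 80.5 ± 6.21 CPM in white, the angiogenic factor Vegfa at 188 ± 17.1 against 142 ± 9.72 CPM, and Egln3, an oxygen-sensing prolyl hydroxylase, at 24.3 ± 7.75 against 12.2 ± 4.23 CPM. Flt1, a receptor of vascular endothelial growth factors, went the other way, at 223 ± 23.8 CPM in green and 353 ± 47.5 CPM in white. The mean log2 level of the whole list, relative to all libraries, was 0.236, -0.028 and 0.076 in the green libraries and -0.185, -0.095 and 0.02 in the white ones, so that the groups overlapped. In edgeR 4 members passed adjusted over the list alone and 0 over all genes, where DESeq2 called Ddit4 (adjusted p = 0.00558) and Flt1 (0.0315). The self-contained fry test, in its directional form, did not call the list (adjusted p = 0.206, the highest of its alternatives, which began at 9.35e-05).

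The lens list rose in green as well, with 17 of 19 members higher and a median log2 difference of 0.845 (adjusted p = 1.79e-07), a call lost with an estimated correlation (adjusted p = 0.232). Cryaa, which encodes alpha-A crystallin, a structural protein of the lens that the retina also expresses, was at 21, 33.1 and 23.4 CPM in the green libraries and at 0.693, 18.1 and 2.4 CPM in the white ones. Cryba2 differed by 1.502 ± 0.439, Crybb3 by 0.80 ± 0.24 and Cryz by 0.46 ± 0.15 on the log2 scale; 0 members passed, over the list alone or over all genes, in edgeR. The ribosomal protein list fell, with 48 of 53 members lower and a median log2 difference of -0.11 (adjusted p = 8.88e-06), a call lost with an estimated correlation (adjusted p = 0.747), with counts summed per animal number (0.109), and without library 2 of green or library 2 of white, where the highest adjusted p was 0.183. Rpl35 was at 251 ± 11.4 CPM in green and 289 ± 23.4 CPM in white, whereas Rpl12 was at 188 ± 31.4 against 149 ± 14.0 CPM, and edgeR called 0 of the 53.

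**Figure D2:**
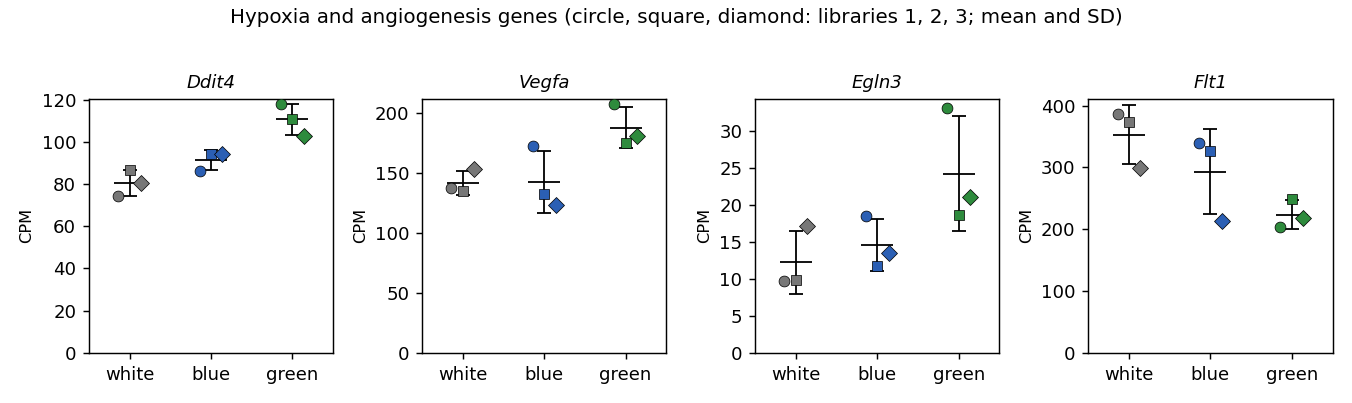
Levels in CPM (y axis) of 4 members of the hypoxia and angiogenesis list by light group (x axis), with a symbol per library and bars for mean and SD of 3 libraries. In each panel, drawn for the members with the smallest p, the 3 green libraries lie apart from the 3 white ones, above them for Ddit4, Vegfa and Egln3 and below them for Flt1, and over all genes edgeR called none of the 4 and DESeq2 called Ddit4 and Flt1.

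Under blue light, LOC101788254 was again the single gene to differ from white light, with 81, 119 and 108 counts in the blue libraries and 1.44 ± 0.268 CPM, at least 96.1-fold above the floor of the white group (edgeR adjusted p = 0.0136). Of the 20 genes with a symbol and the smallest p, 11 were higher and 9 lower in blue, all without overlap. In edgeR none passed (adjusted p from 0.193 to 0.67), and 18 of the 20 were among the genes that DESeq2 called, Cdh23 and Znf667 included. Cdh23, a cadherin of the links within sensory hair bundles, was at 78.5 ± 4.03 CPM in blue and 127 ± 8.88 CPM in white, a log2 difference of -0.70 ± 0.10 (adjusted p = 0.193). Pxmp2, a protein of the peroxisomal membrane, differed by -0.64 ± 0.10, the zinc finger gene Znf667 by -1.79 ± 0.28 and Rbfox1 by -0.89 ± 0.15. Higher in blue were Txnip, the thioredoxin-interacting protein, at 31.5 ± 2.43 against 16.4 ± 3.84 CPM, Fam129b at 31.4 ± 6.01 against 16.8 ± 0.620 CPM, and Cbx7, a Polycomb group gene, at 167.5 ± 27.7 against 105 ± 20.4 CPM. Tead3, a partner of the Hippo pathway's coactivators, was at 84.7, 94.9 and 25.1 CPM in the white libraries and between 17.5 and 23.3 CPM in the blue ones. At an unadjusted p under 0.05 stood 689 genes, 382 higher and 307 lower, under the 773 that chance gives, and 9.9% of genes did not overlap. Other splits of the blue and white libraries into 3 and 3 gave from 248 to 1840 genes at that p. The call of LOC101788254 was lost without library 2 of green (adjusted p = 0.0508) or library 2 of blue (0.0874), with counts divided by 4 (0.14), in a fit of the 6 libraries alone (0.0597) and in voom (0.489). DESeq2 called 28 genes, 17 higher and 11 lower. Over all alternatives the adjusted p of LOC101788254 ran from 1.14e-08 to 0.489. The count of genes was 4 without library 1 of green, 2 without library 1 of blue, 3 without library 3 of blue, and 2, 3 and 7 without library 1, 2 or 3 of white.

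Of the gene lists, 4 passed between blue and white, and none of the 4 did with an estimated correlation, where the smallest adjusted p was 0.677. The lens list rose, with 17 of 19 members higher and a median log2 difference of 0.89 (adjusted p = 6.07e-06; 0.677 with an estimated correlation). Cryba4 was at 4.56 ± 1.92 CPM in blue and 1.22 ± 1.505 CPM in white. The potassium channel list fell, with 21 of 24 members lower and a median of -0.13 (adjusted p = 1.01e-04; 0.677 with an estimated correlation). Kcna2, a voltage-gated potassium channel gene, was at 48.2 ± 3.57 CPM in blue and 65.4 ± 15.7 CPM in white. Müller glia markers rose, with 12 of 16 members higher (adjusted p = 0.0232; 0.964 with an estimated correlation), among them Crym at 281 ± 39.8 against 199 ± 20.2 CPM and Vim at 1311 ± 89.1 against 1143 ± 88.6 CPM. Crym passed in edgeR adjusted over the list alone, and over all genes no member of these lists did. Ribosomal proteins rose, with 42 of 53 higher and a median of 0.05 (adjusted p = 0.0232; 0.964 with an estimated correlation). The Müller glia call was lost without library 3 of blue or library 3 of white (highest adjusted p = 0.938), with the level of pigment epithelium genes (0.096) or the "-B" suffix (0.493) as a covariate, and without both "-B" libraries (0.964). The ribosomal call was lost without library 1 of green, 2 or 3 of blue, or 1 or 3 of white (highest 0.916), with counts summed per animal number (0.446), with the "-B" suffix as a covariate (0.752) and without both "-B" libraries (0.817).

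Green and blue light, the opposed treatments of the design, differed in 0 genes at an adjusted p under 0.05 in edgeR (smallest 0.333). An unadjusted p under 0.05 was reached by 1110 genes, 636 of them higher in green, against 773 expected by chance. Other splits of the green and blue libraries into 3 and 3 gave from 217 to 1461 such genes, so 1110 lies within their range. Groups did not overlap for 14.2% of genes, where chance gives 10%. DESeq2 called 48 genes, 35 higher and 13 lower in green, and voom 0. Of the 20 genes with the smallest p, 16 were higher and 4 lower in green, with edgeR adjusted p from 0.333 to 0.488, and DESeq2 called 19 of the 20. Cdh23 was at 126 ± 16.2 CPM in green and 78.5 ± 4.03 CPM in blue, Myo15b at 13.5 ± 3.50 against 5.32 ± 0.643 CPM, and Asic1, an acid-sensing ion channel, at 31.3 ± 3.29 against 20.1 ± 1.11 CPM. Impg1, a proteoglycan of the matrix between photoreceptors, differed by 0.51 ± 0.10 on the log2 scale, the calcium release channel gene Ryr1 by 0.56 ± 0.11, Leng8 by 0.53 ± 0.10 and Igfbp5 by 0.93 ± 0.19. Lower in green were Olfml1 at 0.446 ± 0.168 against 2.55 ± 1.02 CPM, the calcium-binding protein gene Scgn with a log2 difference of -0.58 ± 0.12, and P2rx6, a purinergic receptor gene, with -0.53 ± 0.10. Without library 2 of green, 4 genes passed, and without library 3 of blue 2 genes did; without library 1 of green, of blue or of white 1 gene passed in each case.

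Of the gene lists, 9 passed between green and blue, 5 higher and 4 lower in green, and none of the 9 did with an estimated correlation (smallest adjusted p = 0.0949). Glycolysis genes rose in green, with 19 of 21 members higher (adjusted p = 0.00186; 0.378 with an estimated correlation), among them hexokinase Hk2 at 720 ± 28.4 against 590 ± 60.6 CPM and Pgk1 at 948 ± 66.2 against 823 ± 10.3 CPM. Calcium and sodium channels rose, with 17 of 18 higher (adjusted p = 0.00224; 0.571 with an estimated correlation). Cacna1f was at 719 ± 58.9 CPM in green and 575 ± 23.7 CPM in blue, and Cacna2d4, its auxiliary subunit in photoreceptors, at 427 ± 25.6 against 329 ± 20.6 CPM; these 2 passed over the list alone. Potassium channels rose, with 19 of 24 higher (adjusted p = 0.0111; 0.567 with an estimated correlation), GABA and glycine genes with 18 of 25 (0.0256; 0.571 with an estimated correlation) and the hypoxia list with 14 of 19 (0.0323; 0.378 with an estimated correlation). Ribosomal proteins fell, with all 53 lower and a median log2 difference of -0.145 (adjusted p = 1.29e-11; 0.571 with an estimated correlation). Müller glia markers fell with 12 of 16 lower (0.0115; 0.567 with an estimated correlation), including Apoe at 704 ± 94.3 against 981 ± 65.1 CPM and Clu at 2153 ± 312 against 2775 ± 146 CPM. Interferon and antigen presentation genes fell with 12 of 15 lower (0.0256; 0.0949 with an estimated correlation), and oxidative phosphorylation genes with 16 of 19 (0.0451; 0.824 with an estimated correlation). By the mean log2 level of a list in each library, relative to all libraries, the interferon list alone of the 9 set the 3 green libraries apart from the 3 blue ones. Library 3 of green had the lowest level of these 6 libraries for glycolysis (-0.059) and potassium channels (-0.138). For calcium and sodium channels (-0.093) and for GABA and glycine (-0.115) it lay below libraries 2 and 3 of blue. For ribosomal proteins it lay at 0.073, above library 1 of blue at -0.078. Over all genes edgeR called 0 members of these lists, and DESeq2 called Cacna2d4 (adjusted p = 0.041). With counts summed per animal number the hypoxia call was lost (adjusted p = 0.134), as was that of oxidative phosphorylation (0.328). In voom that of GABA and glycine was lost (0.0789), in a fit where the correlation within animal numbers was set to 0 and libraries counted as independent. In a fit of the 6 libraries alone the hypoxia call was lost as well (0.0531), and so was that of oxidative phosphorylation. The latter was also lost with no filter, DESeq2's size factors, upper-quartile scaling and DESeq2's Wald test. With the filter of at least 5 CPM the calls of oxidative phosphorylation and interferon were lost. With the level of pigment epithelium genes as a covariate 5 of the 9 calls were lost, those of GABA and glycine (0.0593), hypoxia (0.0969), Müller glia (0.0969), interferon (0.171) and oxidative phosphorylation (0.338). With the "-B" suffix as a covariate 7 of the 9 were lost, those of interferon (0.0508), potassium channels (0.0508), calcium and sodium channels (0.0671), hypoxia (0.0828), Müller glia (0.113), GABA and glycine (0.164) and oxidative phosphorylation (0.428). Without both "-B" libraries those of hypoxia (0.139), GABA and glycine (0.32) and oxidative phosphorylation (0.983) were lost. Calls that ended when a library was left out were those of GABA and glycine (green 1, blue 1; highest adjusted p = 0.34), hypoxia (green 1, blue 2, blue 3, white 2; 0.166), potassium channels (green 2, blue 1; 0.252), interferon (green 3, blue 2; 0.0874) and oxidative phosphorylation (green 1, blue 2, blue 3 and each white library; 0.978).

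**Figure D3:**
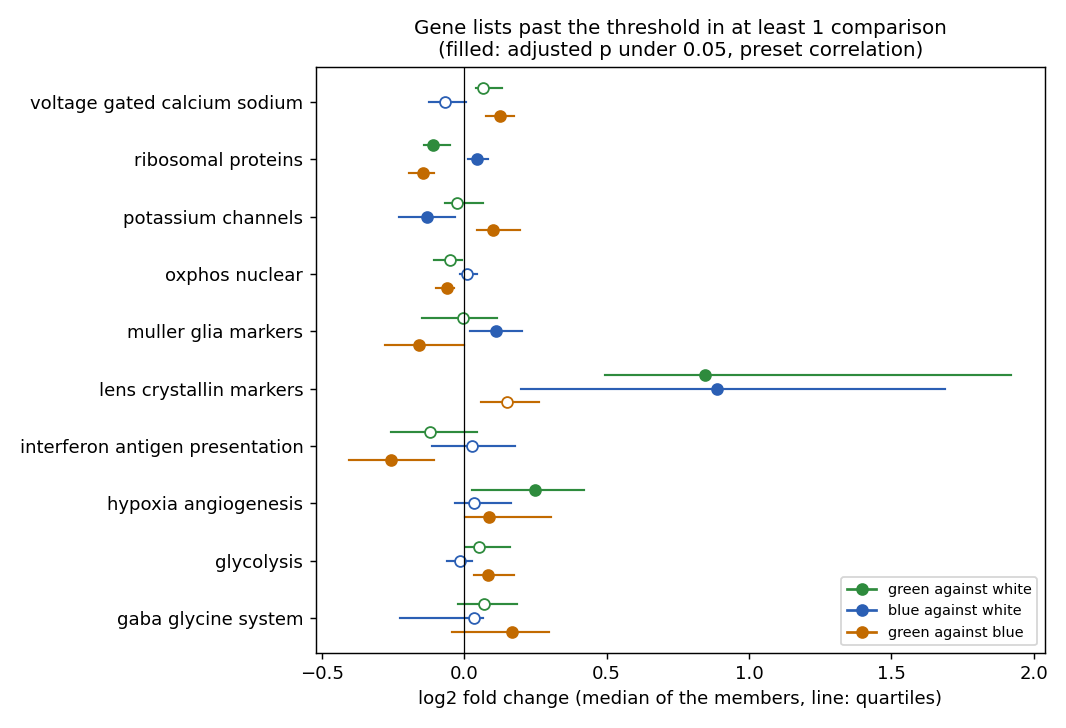
Median log2 fold change (x axis, lines for the quartiles of the members) of each gene list (y axis) that passed in at least 1 of the 3 comparisons, coloured by comparison. Filled points had an adjusted p under 0.05 with the preset correlation; the lens list lies furthest from 0, with medians of 0.845 and 0.89 in the coloured lights against white, and the other medians lie between -0.26 and 0.25.

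Genes of light sensing, dopamine and the clock, named in advance, stayed below the threshold of edgeR in each comparison. The short-wavelength cone opsin Opn1sw was at 641 ± 49.3 CPM in green, 598 ± 50.3 CPM in blue and 572 ± 15.7 CPM in white, and in the same order the middle-wavelength opsin Opn1mw was at 623 ± 62.3, 651 ± 51.4 and 684 ± 61.3 CPM. Melanopsin, Opn4, was near 9.16 ± 1.47, 9.18 ± 4.19 and 7.24 ± 2.74 CPM. Th, the rate-limiting enzyme of dopamine synthesis, was at 36 ± 6.26, 32.8 ± 9.53 and 28.6 ± 3.43 CPM, and the activity-dependent transcription factor Egr1 at 23.4 ± 11.9, 23.3 ± 14.7 and 21.5 ± 3.61 CPM. Vip, a neuropeptide of amacrine cells, was at 4.405 ± 1.79 CPM in green, 1.86 ± 0.1996 CPM in blue and 2.12 ± 1.198 CPM in white, and its log2 difference between green and blue of 1.25 ± 0.40 did not pass (adjusted p = 0.623). Aanat, the penultimate enzyme of melatonin synthesis, differed by 0.34 ± 0.13 between green and white (adjusted p = 0.84), and the clock output gene Dbp by -0.24 ± 0.09 between green and blue (0.654). Bmp2 and Tgfb2, growth factors studied in eye growth, differed from white by no more than 0.17 on the log2 scale in size, with SE of 0.35 and 0.09. The median SE over all genes was 0.142 on the log2 scale.

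Lists of these and other functions did not pass between green and white. The adjusted p was 0.236 for rod and 0.598 for cone phototransduction, 0.468 for the visual cycle and pigment epithelium, 0.703 for Müller glia (which passed in the other comparisons), 0.591 for microglia, 0.598 for vascular cells, 0.599 for melanopsin cells, 0.907 for the circadian clock, 0.62 for dopamine, 0.468 for retinoic acid, 0.761 for immediate early genes and 0.598 for eye growth signals. For vascular cells and immediate early genes the median log2 difference (0.036 and 0.027) was positive while the mean was negative and the test pointed lower. Adjusted over the list alone, 2 retinoic acid genes, 1 cone gene and 1 vascular gene passed in edgeR, and over all genes 0 did, where DESeq2 called the cone channel gene Cngb3 (adjusted p = 0.0184) and Flt1. Between green and blue, the visual cycle and pigment epithelium list had 14 of 19 members lower in green (adjusted p = 0.124), and the cone list 9 of 16 higher (0.236).

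**Figure D4:**
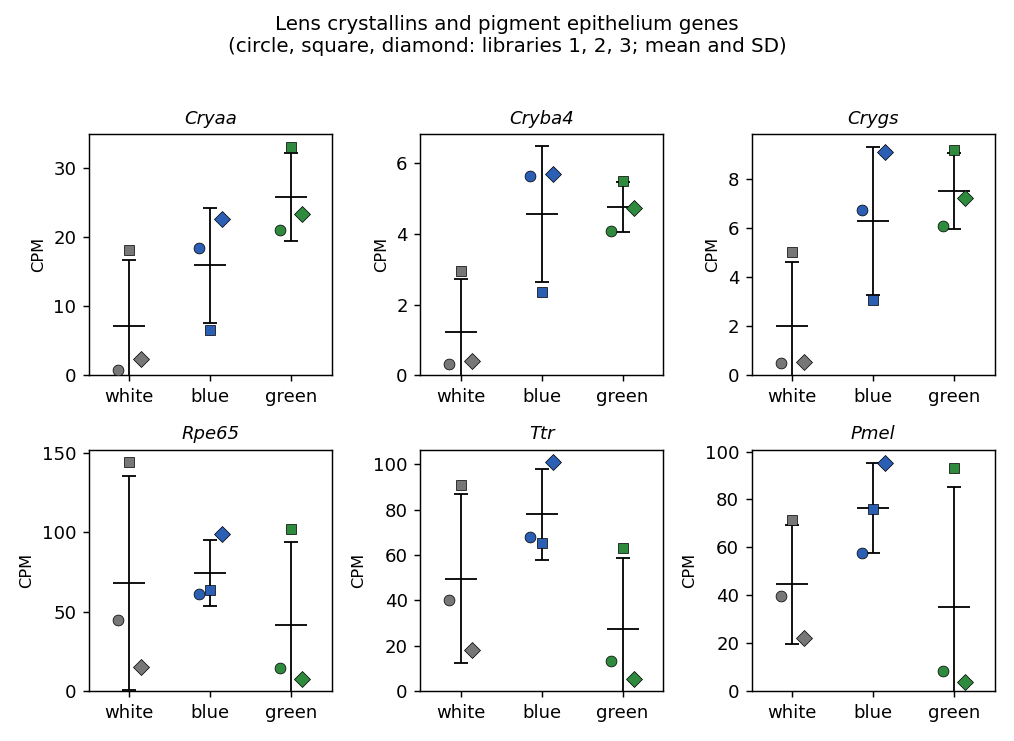
Levels in CPM (y axis) of 3 lens crystallins (upper panels) and 3 pigment epithelium genes (lower panels) by light group (x axis), with a symbol per library and bars for mean and SD of 3 libraries, drawn from 0 upward. Cryaa is at 0.693 and 2.4 CPM in white libraries 1 and 3 and at 18.1 CPM in white library 2, and Rpe65 runs from 7.76 to 102 CPM within the green group.

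The series title asks about opposite effects, so the fold changes of both coloured lights against white were set side by side. Across genes their Pearson correlation was 0.509. In simulations all libraries were drawn unchanged, and both groups were set against the same simulated white libraries. These gave 0.503 ± 0.0171 (SD of 50 simulations, range 0.456 to 0.544). Each gene was drawn independently, so variation that genes share is left out and the simulated spreads and ranges can be too narrow. The covariance was 0.0807 against 0.0595 ± 0.00373 simulated, a difference of 0.0212, while the variances were also larger than simulated (0.154 against 0.118 for green, 0.163 against 0.119 for blue). Both contrasts had an unadjusted p under 0.05 for 183 genes in the same direction and for 6 in opposite directions. Simulations gave 162 and 1.72 on average and up to 186 and 6. Independent lists would share 20.5 and 19.6. The same sign in both contrasts was found for 61% of genes, fewer than the 66.7% of the simulations. At the adjusted threshold of edgeR 1 gene, LOC101788254, was called in both, in the same direction, and 0 genes in opposite directions. The white libraries cannot be split into parts of at least 2, so part of any excess can come from the shared white libraries. Genes whose 3 groups did not overlap with white in the middle numbered 13 with green highest and 19 with blue highest, where chance gives 9.21 of each. The ratio to chance of both together, 1.74, fell to 0.805 without library 3 of blue. Among the latter was P2rx6, at 27.2 CPM in blue, 22.2 in white and 18.9 in green. Among the former was Asic1, at 31.3 CPM in green, 25.6 in white and 20.1 in blue. With blue in the middle there were 12 and 15 such genes, and with green in the middle 10 and 11.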

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

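The counts divided by 4, the "-B" suffix, the pigment epithelium level and the residual components were alternatives chosen after seeing the data; the others were chosen before. No paired analysis was possible because no label states a pair across light groups; library 1 of blue (2R-23) and library 3 of white (R-23) share part of a label, and whether they come from the same animal is not stated. Other pseudocounts and quantile normalization of log2 values apply to normalized values and were not run on counts. Taking every library as independent is the edgeR fit itself. In voom the correlation within animal numbers was estimated at -0.135 and was therefore set to 0.

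In edgeR 1, 1 and 0 genes passed for green against white, blue against white and green against blue, and 1 in the joint test. No filter, DESeq2's size factors, upper-quartile scaling and robust empirical Bayes gave the same 4 counts, and the scalings moved the median log2 fold change by at most 0.0073. DESeq2's Wald test gave 24, 28, 48 and 82 genes. In simulated data it made 40 false calls where edgeR made 10. Many genes were truly changed there, so the 40 cannot be set directly against the real counts. Voom gave 0, 0, 0 and 0, and so did counts divided by 4. A filter of at least 5 CPM also gave 0, 0, 0 and 0, because it removes LOC101788254, which then has no value. Summed counts per animal number gave 1, 1, 0 and 0. The 6 libraries of a comparison alone gave 0, 0 and 1 (Mapk8). With the "-B" suffix as a covariate the counts were 1, 3, 1 and 2, and without both such libraries 10, 12, 0 and 12. The pigment epithelium covariate gave 1, 2, 0 and 1, the first residual component 2, 2, 0 and 1, and the first 2 components 7, 4, 44 and 18. The cause of these differences was not tested.

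Without 1 library the counts ran from 0 to 6 (green against white), 0 to 7 (blue against white), 0 to 4 (green against blue) and 0 to 6 (joint test). The highest were those without library 3 of white (6, 7 and 6) and, for green against blue, library 2 of green (4). The joint test gave 0 without library 2 of blue or library 2 of white, 2 without library 1 or 2 of green, library 3 of blue or library 1 of white, and 3 without library 3 of green.

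Of the gene lists, 3, 4 and 9 passed in the 3 comparisons. With an estimated correlation 1, 0 and 0 passed, and with the directional fry test 0, 0 and 0, where the smallest adjusted p was 0.206, 0.995 and 0.137. The mixed fry test, which counts members moving either way, called 2, 0 and 0 lists. Between green and white these were hypoxia and interferon (mixed fry adjusted p = 0.0346 for both). The "-B" covariate gave 4, 2 and 2 lists, the fit without both "-B" libraries 7, 2 and 9, and the pigment epithelium covariate 7, 3 and 8. Of the 8, 4 were among the 9 called without the covariate. Without 1 library the counts ran from 3 to 9, from 2 to 6 and from 7 to 12. Green against white had 5 lists without library 1 of green, 6 without library 2 of green or library 3 of white and 9 without library 3 of green, and blue against white had 2 without library 3 of blue or library 3 of white. Of 26 alternatives, the hypoxia list between green and white kept its call in 25, the lens list in 24 in both comparisons with white, and the oxidative phosphorylation list in 8. Between green and blue, glycolysis and ribosomal proteins alone passed with the "-B" covariate. No list changed direction past the threshold.

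The correlation of both coloured lights' fold changes, 0.509, was 0.367 with the filter of 5 CPM, 0.527 with separate fits, 0.63 without the "-B" libraries, 0.352 with the pigment epithelium covariate and 0.418 with 2 residual components. Without 1 library it ran from 0.402 (library 1 of green) to 0.707 (library 3 of white). It was 0.402 to 0.44 without a coloured library and 0.629 to 0.707 without a white one. The correlation that shared white libraries alone give changes with the number of libraries per group. Simulations were run only with 3 libraries per group. The values with libraries left out can therefore not be set against the simulated 0.503 or read as an effect of a particular library. The ratio to chance of genes ordered with white in the middle, 1.74, ran from 0.805 (without library 3 of blue) to 2.01 (without library 1 of blue).

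For named genes, 191 results under 24 alternatives gave 4541 values. Of these, 4450 stayed on their side of the threshold, 81 newly passed, 10 no longer passed and 0 reversed past the threshold, while 111 below it changed sign. Depth limits low genes most: 3 counts correspond to 0.04 to 0.0483 CPM per library. In simulated data edgeR recovered 31.2% of 1.5-fold changes, so differences of that size can be missed with 3 libraries per group.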

Other observations

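The tests and the genes singled out in this part were chosen after the results were seen, except that counts over other splits of the libraries belong to the plan of every comparison.

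Several genes set the white libraries with animal number 6 (libraries 1 and 2) apart from library 3 of white. LOC101787273 and Tead3 also set them apart from the green and blue libraries. LOC101787273 had 0 CPM in both and 4.41 CPM in library 3 of white, and between 2.92 and 4.92 CPM in the green and blue libraries. Tead3 was at 84.7 and 94.9 CPM in both and at 17.5 to 33.2 CPM elsewhere. Mlc1, a membrane protein of astrocytes and Müller glia, was at 34.4 and 42 CPM against 7.82 CPM in library 3 of white, and Wbp1l at 32 and 32.1 against 72.8 CPM. LOC111758275, a protein-coding locus without a symbol, was at 7.96 ± 3.21 CPM in green, 7.58 ± 2.69 in blue and 1.71 ± 0.551 in white, and passed in DESeq2 against white in both coloured lights (adjusted p = 1.16e-06 and 3.18e-06) but not in edgeR. Vip had 5.41, 2.34 and 5.46 CPM in the green libraries and 1.3, 1.56 and 3.49 CPM in the white ones. In the blue libraries Vip had 1.63, 1.98 and 1.97 CPM, near libraries 1 and 2 of white.

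With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In 4 of the 10 for green against white at least 1 gene passed, the real count being 1 and the highest other 10, and 8 gave at least the real 3 lists (highest other 17). For blue against white 3 splits gave 1 gene or more (real 1, highest other 1) and 6 gave 4 lists or more (highest other 10). For green against blue the real count of genes was 0, which all 10 splits reach by construction, so that count tests nothing (highest other 1), and 3 gave at least the real 9 lists (highest other 15). For the joint test, 36 of 100 splits drawn from 280 gave at least the real 1 gene, so chance is not excluded, and the highest other gave 138. For genes ordered with white in the middle, 102 of 840 arrangements gave at least the real 32 (highest other 298), so chance is not excluded there either.

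The split with 138 genes, and 4142 at an unadjusted p under 0.05, joined library 1 of green, of blue and of white, then libraries 2 and 3 of green with library 3 of white, then libraries 2 and 3 of blue with library 2 of white. It crosses the light groups and points to a structure of the libraries that no label names. The ribosomal protein list follows part of this split: libraries 2 and 3 of blue and library 2 of white had the highest mean log2 levels relative to all libraries (0.131, 0.152 and 0.112). Their difference from the rest was 0.198. Being the 3 highest libraries, they give the largest difference of all 84 splits into 3 and 6 by construction, so that rank tests nothing. The levels of libraries 2 and 3 of green and library 3 of white (-0.161, 0.073 and -0.028) overlapped those of the first set (-0.146, -0.078 and -0.055). Green against the rest had an exact p of 0.179 over 84 splits (two-sided, adjusted p = 0.322). The next splits gave 9, 6 and 5 genes. The first 2 components of the residuals held 24.8% and 18.8% of the residual variance. With 6 residual degrees of freedom only 6 components share this variance, so sizeable shares arise even without a structure.

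LOC101788254 had no counts in the 3 white libraries. Low depth is argued against, since 87.8 counts were expected in the shallowest white library at the rate of the coloured ones. Genes on or off between libraries whatever their light stay open, since 4 of the 83 other sets of 3 libraries, all of mixed light, had a gene with no counts in them and over 0.2 CPM elsewhere, a share of 0.0482. The lowest unscaled level of these genes elsewhere was 15.5 CPM (LOC106026990), 0.855 (LOC100721370), 0.213 and 0.209 CPM, against 0.872 CPM for LOC101788254. A variant carried by the animals, a difference in reads shared with a similar locus, and the light itself stay open and untested, and the white libraries carry only 2 animal numbers.

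Lens crystallins were lower in white libraries 1 and 3 than in library 2 of white and in the coloured lights. A single outlying library is argued against, as the list's adjusted p for green against white stayed at or below 0.000395 without any 1 library. These values use the preset correlation of 0.01, and the call is lost with the estimated correlation of 0.332 (adjusted p = 0.232). Lens tissue carried into some retina samples is a candidate explanation: the 6 lens genes other than crystallins were lower in white as well, by a mean log2 difference of -0.393 (two-sided exact p = 0.0119 over 84 splits, the smallest they can give, adjusted p = 0.143 over 18 such tests). The crystallins differed by -1.989 (exact p = 0.0238, adjusted p = 0.143), and the light itself was not tested apart from this and stays open.

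The hypoxia and angiogenesis list was higher in green than in white light. Pigment epithelium carried into some samples as the whole cause is argued against by an adjusted p of 0.00192 with its marker level as a covariate. With the "-B" suffix as a covariate the adjusted p was 9.35e-05. That fit cannot decide on a difference of the "-B" libraries, since 1 green and 1 white library carry the suffix and it hardly moves this contrast. The list kept its call without both such libraries. A single outlying library is argued against by an adjusted p of at most 0.0262 without any 1 library. Chance is not excluded, as 12 of 84 splits into 3 and 6 gave a difference of the mean log2 level as large as the real 0.142 between green and the rest (highest other 0.204; two-sided exact p = 0.143, adjusted p = 0.322). An effect of light stays among the open explanations.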
